A study of Homo sapiens with 4 samples.

How the data were processed

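Polyadenylated RNA of MDA-MB-231 cells, an established human triple-negative breast cancer line, was sequenced on a nanoball platform in 4 libraries, 2 of cells treated with a compound labelled APA (40 µM, 24 h) and 2 of control cells. The labels call the control treatment PBS and the series' design text names DMSO as the vehicle, so the group is called control here. If control cells received PBS and APA was given in DMSO, an effect of the vehicle could not be told apart from that of APA. What the abbreviation APA stands for is not given in the sources used here. The labels number the libraries 1 and 2 within each group and do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

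The authors deposited 1 table of estimated counts per gene (expected counts, with values that need not be whole) and 1 table of FPKM for the same genes. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM and genome build GRCh38.p13, with no role or order, and the version of RSEM, the annotation and the strand setting are not given in the sources used here. The deposited expected counts were not normalized, and 48.2% of them were not whole numbers. The deposited FPKM values were scaled by the authors for gene length and library size, and they were used only for alternatives. The design had assumed counts; because the values were expected counts, they were rounded to whole numbers before testing. Expected counts divide the reads that near-identical genes share, so values of single members of such families (the MT1 metallothioneins, AKR1C genes, CXCL1 to CXCL3, HSPA1A and HSPA1B, ferritins and their pseudogenes, histones) are uncertain. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be assigned with certainty either.

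The tables listed 17059 genes by Entrez identifier and symbol. Of these, 16997 matched the reference gene table by Entrez identifier, 16933 of them as protein-coding, and 2 of the genes of interest were found under older symbols. The reference table was of another patch release than the authors' build, so it served for names only and no coordinates are given. Library totals lay between 20000788 and 20215114 expected counts. Levels are given as CPM, counts scaled to library size, and at this depth changes of genes below 1 CPM are imprecise.

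Gene-wise tests used edgeR 4.0.16 in R 4.3.3: TMM normalization, the default expression filter, a robust quasi-likelihood fit with treatment as its term, a two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are APA minus control, and each standard error (SE) is the absolute log2 fold change divided by the square root of F. Expression levels are CPM on TMM-scaled library sizes, as mean ± SD of 2 libraries. Before the data were examined, 37 gene lists with 867 entries were fixed, of which 817 entries were in the tables. The list of 13 mRNAs encoded in the mitochondrial genome had 0 entries in the tables and was not analysed here. The other 36 lists had at least 3 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 36 lists, and again with a correlation estimated per list. The estimated setting rests on the 2 residual degrees of freedom of the 4 libraries, so it has little power to call any list. Member counts per direction were taken from the adjustment over all genes tested, and again from p-values adjusted over the list alone.

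The rule for genes named in the text was also fixed before the data were examined. It takes the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM and no overlap between the groups, without uncharacterised or antisense genes. It also takes up to 3 called members of each list with a mean of at least 1 CPM, by size of change, or the most abundant tested member where none was called, and any tested metallothionein or zinc transporter gene with MTF1. Genes said to lead a list, or to change most in it, are ranked among called members with a mean of at least 1 CPM. A gene that the rule takes is not reported here. Another 31 genes were chosen after their values were seen, and the text says so where they appear.

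The procedures were tested on simulated data drawn from the means, library sizes and dispersion trend of these samples, without scatter of single genes around that trend. Among 13593 simulated genes tested, the fit recovered 66% of genes changed 1.25-fold, 80% of those changed 1.5-fold, 85.7% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls among 172. Few simulated genes were changed, whereas 53.5% were called in the data, so these rates may not hold for the data. Of the list tests on simulated data with the glycolysis list shifted by -0.5, camera with the preset correlation called that list (adjusted p = 4.75e-36) and camera with an estimated correlation missed it (adjusted p = 0.185). Simulated genes were drawn independently, and genes outside that list were left unchanged. The simulation therefore cannot show whether the preset correlation holds for genes that vary together.

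Alternatives planned before the data were examined were RLE and upper-quartile normalization, no filter and a stricter filter (at least 5 CPM in at least 2 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, log2(FPKM + 1) without that filter, and each library left out in turn. For lists they were an estimated correlation, fry, the block, RLE factors, no filter, FPKM and each library left out. A correction of each library for GC content and transcript length (natural splines with 5 degrees of freedom, median values over the protein-coding GENCODE transcripts of each gene) and 16 gene families defined by symbol were added after the data had been seen. Each replication and mitosis gene was also matched to the 10 genes outside both lists that were nearest to it in scaled GC content and log2 length. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.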

Results

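Gene expression was measured by RNA-seq in MDA-MB-231 cells, a triple-negative breast cancer line, after 24 h with 40 µM APA (2 libraries) or with the control treatment (2 libraries). Library totals were 20206940 and 20215114 expected counts for APA replicates 1 and 2, and 20080060 and 20000788 for control replicates 1 and 2. The 10 most abundant genes of each library took 5.45% and 5.30% of the counts in APA and 4.42% and 4.41% in control. Log2(CPM + 1) values correlated across genes at r = 0.998 within each group and 0.989 to 0.990 between groups, with the caution that genes are not independent replicates. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.66 in APA and 1.98 in control, against 59.4 to 63.2 between libraries of different groups.

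The series is titled as a study of zinc metabolism in breast cancer, and its 1 comparison asks which transcripts differ between APA-treated and control cells. The largest increase among genes with at least 5 CPM was that of GDF15 (Entrez 9518), a stress-induced cytokine, at 85.8 ± 7.03 CPM in APA against 6.56 ± 0.044 in control (SD, n = 2 libraries each). This was 13.1-fold higher, with a log2 fold change of 3.71 ± 0.085 (SE). Other transcripts that rose strongly included those of the cytokine IL24 (3.35 ± 0.18), the lysosomal protein LAMP3 (3.26 ± 0.099) and the kinase STK32A (3.05 ± 0.15). They were followed by the interstitial collagenase MMP1 (2.84 ± 0.047), the calcium-binding protein S100P (2.83 ± 0.14), cyclooxygenase 2 (PTGS2, 2.67 ± 0.055), the V-ATPase subunit ATP6V0D2 (2.58 ± 0.16) and the glutathione-degrading enzyme CHAC1 (2.54 ± 0.081). The largest decrease above the same limit was that of the calcium-regulated NADPH oxidase NOX5 (Entrez 79400), from 66.6 ± 0.378 CPM in control to 6.20 ± 0.355 in APA, 10.7-fold lower (log2 fold change -3.42 ± 0.086). The helicase PIF1 (-3.33 ± 0.16) and the ubiquitin ligase NEURL1B (-2.90 ± 0.18) followed. Next were the mitotic genes KIF20A (-2.75 ± 0.056), PLK1 (-2.67 ± 0.062), PSRC1 (-2.39 ± 0.084), FAM83D (-2.39 ± 0.079), DLGAP5 (-2.32 ± 0.051) and CENPE (-2.22 ± 0.051), with SHISA3 at -2.36 ± 0.14.

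With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7348 of 13732 genes tested (53.5%) were called, 3662 of them higher and 3686 lower in APA. Most of these changes were small, with a median absolute log2 fold change of 0.36. A change of at least 2-fold was called for 679 genes (371 higher, 308 lower), and one of at least 4-fold for 100 genes (60 higher, 40 lower). Both APA libraries lay on the same side of both control libraries for 74.4% of genes tested, against 33.3% by chance. The count past 2-fold fell to 408 with the stricter expression filter, and it was 300 on log2(FPKM + 1) values, a scale that compresses changes of genes with low values.

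**Figure D1:**
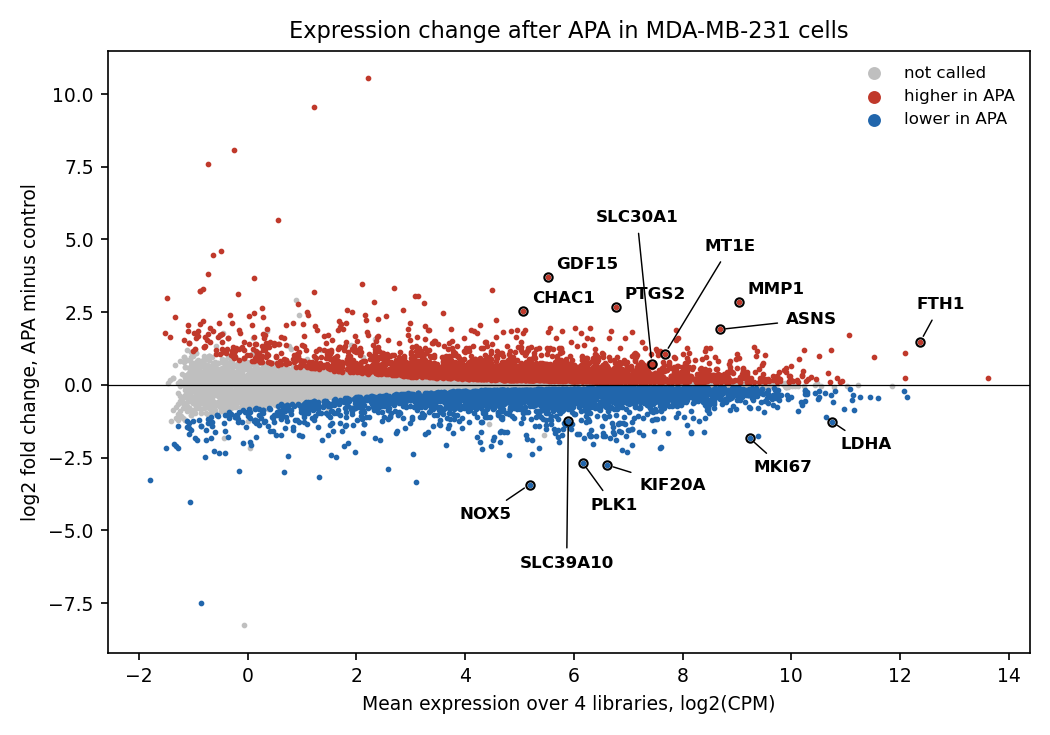
Log2 fold change (APA minus control) of each of the 13732 genes tested against mean expression over the 4 libraries in log2(CPM), with genes called higher in red, called lower in blue and not called in grey. Labelled points include GDF15 at 3.71, MMP1 at 2.84, NOX5 at -3.42 and KIF20A at -2.75. Fitted values of genes with 0 counts in 1 group, at the left, depend on a prior count.

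Among genes of zinc handling, 4 of 5 metallothionein genes and the plasma membrane zinc exporter gene SLC30A1 were higher in APA, and the zinc importer gene SLC39A10 was lower. MT1E (Entrez 4493) stood at 278 ± 11.7 CPM in APA against 131 ± 1.80 in control (SD, n = 2 libraries each; 2.11-fold, log2 fold change 1.08 ± 0.044), and MT1X at 186 ± 15.5 against 95.4 ± 1.47 (0.96 ± 0.048). MT2A, the most abundant of these zinc-binding proteins, rose less, from 1307 ± 74.2 to 1501 ± 74.8 CPM (0.20 ± 0.041), a change not called on unfiltered log2(FPKM + 1) values (limma adjusted p = 0.111), and MT1F rose from a low level, 0.327 ± 0.177 to 1.70 ± 0.037 CPM (2.36 ± 0.41). SLC30A1 (Entrez 7779) increased from 131 ± 2.40 to 215 ± 3.35 CPM (0.72 ± 0.044), and SLC39A10 (Entrez 57181) decreased from 83.7 ± 1.70 to 35.5 ± 3.83 CPM (-1.24 ± 0.062). MTF1, the zinc-sensing transcription factor of metallothionein genes, was higher (0.32 ± 0.060; 63.7 ± 3.12 against 51.1 ± 0.881 CPM).

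Of 5 metallothionein genes tested, 4 rose, 0 fell and MT1A was not called (0.10 ± 0.48), with the same counts adjusted over the list alone. Camera called the list higher (adjusted p = 0.0305), but the adjusted p was 0.445 with an estimated correlation, 0.0556 without APA replicate 1, 0.0513 without control replicate 2 and 0.123 without a filter on low counts. The log2 fold change of MT1F was 3.04 without control replicate 2 and 1.90 without control replicate 1, and reads shared between MT1 genes make its value uncertain. ZIP importer genes went both ways, with 3 of 11 higher and 6 lower, unchanged in number when adjusted over the list alone. The list was not called by camera (adjusted p = 0.368) but was called lower by fry, which does not compare it with other genes (adjusted p = 0.0116). SLC39A14 was higher (0.52 ± 0.043), and SLC39A4 (-0.66 ± 0.16), SLC39A3 (-0.42 ± 0.072) and SLC39A8 (-0.28 ± 0.051) were lower. The ZnT exporter list had 3 of 9 members higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.525): SLC30A1, SLC30A4 (0.33 ± 0.098) and SLC30A7 (0.18 ± 0.056). Some smaller calls of both lists were lost when 1 library was left out, each with its direction kept (adjusted p values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). SLC39A9 (-0.11) lost its call whichever library was left out (-0.0835 to -0.1346; adjusted p 0.0553 to 0.31). SLC39A11 (0.23) lost it without APA replicate 2 (0.20; adjusted p = 0.0838) or control replicate 1 (0.19; 0.159), and SLC39A1 (-0.16) without either of the same libraries (-0.10 and -0.14; 0.0644 each). SLC39A6 (0.16) lost its call without control replicate 2 at nearly the same log2 fold change (0.16; 0.0523), and SLC30A4 without control replicate 1 (0.27; 0.0673). SLC30A7 lost its call without APA replicate 2 (0.083; adjusted p = 0.253) or control replicate 2 (0.15; 0.11).

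**Figure D2:**
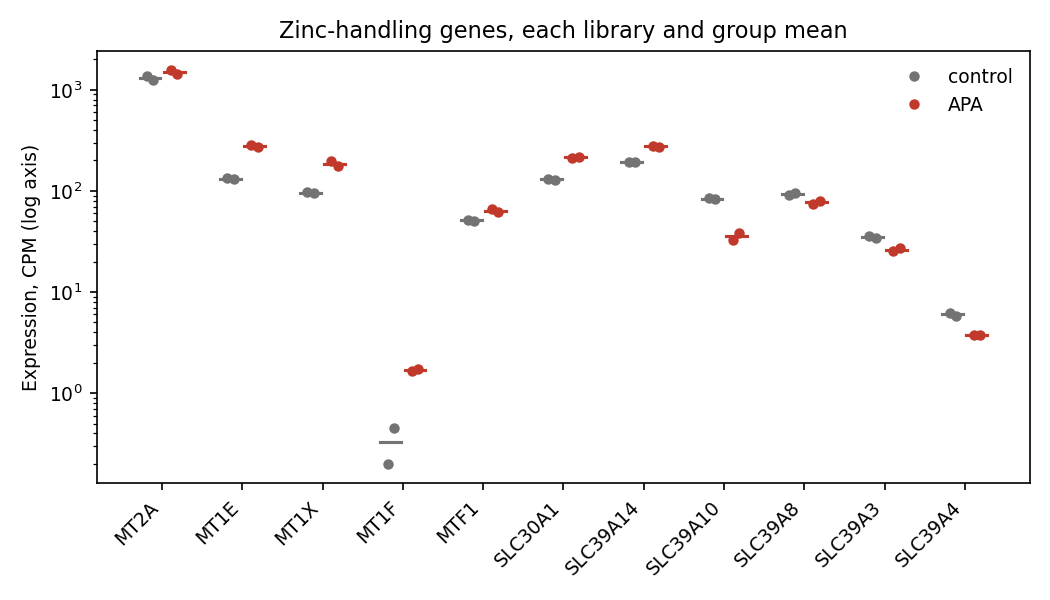
Expression in CPM (log axis) of 11 zinc-handling genes in each of the 4 libraries, control in grey and APA in red, with a bar at each group mean. MT1E (278 against 131 CPM), MT1X (186 against 95.4) and SLC30A1 (215 against 131) lie higher in APA, and SLC39A10 (35.5 against 83.7) lies lower.

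Zinc enzymes and the handling of other metals changed gene by gene. MMP1 rose 7.15-fold, from 130 ± 12.4 to 927 ± 11.6 CPM, and MMP3 (2.14 ± 0.31) and ADAMTS6 (1.54 ± 0.15) rose with it. Of the 20 metalloproteinase and ADAM genes 8 were higher and 7 lower (camera adjusted p = 0.412). The ferritin chains FTH1 (1.48 ± 0.041; 7825 ± 208 against 2798 ± 126 CPM) and FTL (1.11 ± 0.040) were among the most abundant transcripts that rose. The transferrin receptor TFRC, chosen after its value was seen, fell (-0.41 ± 0.040), as did the iron chaperone gene PCBP2 (-0.43 ± 0.042). Iron-handling genes numbered 4 higher and 6 lower of 15 (camera adjusted p = 0.971), and the median of the list (-0.11) and its mean (0.10) differed in sign, with the test pointing up. In the copper list, 4 of 12 were higher, led by the importer gene SLC31A1 (0.61 ± 0.045), and 2 lower (camera adjusted p = 0.378). Of 8 carbonic anhydrase genes, CA13 was higher (0.28 ± 0.074; adjusted p = 0.0586 in DESeq2) and CA9 and CA12 lower (camera adjusted p = 0.378). CA12 fell from 74.0 ± 0.519 to 43.4 ± 1.48 CPM (-0.77 ± 0.060). CA9, also chosen after its values were seen, had 0 counts in both APA libraries against 27 and 17 in control, at least 7.39-fold lower against a floor of 3 counts per library, which covers counting error only. Adjusted over the list alone, the counts of these 4 lists were the same.

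Genes of cell division fell as a group. All 34 mitosis and G2/M genes were lower in APA, with a median log2 fold change of -1.66, and so were all 34 genes of DNA replication and the G1/S transition, with a median of -0.65. KIF20A fell from 171 ± 7.60 to 25.3 ± 1.05 CPM (SD, n = 2 libraries each), the kinase PLK1 from 124 ± 0.20 to 19.4 ± 1.61 CPM and the proliferation marker MKI67, named after its value was seen, from 944 ± 6.06 to 264 ± 3.96 CPM (-1.84 ± 0.041). Among replication genes the largest decreases were those of thymidylate synthase (TYMS, -1.36 ± 0.047), E2F2 (-1.21 ± 0.11) and the origin recognition subunit ORC1 (-1.04 ± 0.078). Both counts were the same adjusted over the list alone, and camera called both lists lower (adjusted p = 1.57e-20 for mitosis and 5.13e-14 for replication). For each of them the adjusted p = 0.274 with an estimated correlation. Mean log2 fold changes of the mitosis and replication lists, -1.64 and -0.68, differed by -0.96 (two-sided permutation test across genes, p = 1e-05, the smallest that 100000 resamples can give). Genes are not independent replicates in that test. Replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, were poorly sampled, with 2 of 12 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.794). H2BC5 was higher (0.64 ± 0.13) and H2BC12 lower (-0.47 ± 0.083).

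Stress-response genes moved in different directions by class. Of 29 ATF4 and integrated stress response genes, 28 rose and 1 fell, with a median of 0.78. CHAC1 rose 5.83-fold (57.4 ± 2.82 against 9.85 ± 0.581 CPM; SD, n = 2 libraries each), the transcription factor gene DDIT3, which encodes CHOP, 3.87-fold (1.95 ± 0.056) and asparagine synthetase (ASNS) 3.75-fold (1.91 ± 0.043). DDIT4, named after its value was seen, was lower (-0.17 ± 0.040). ER chaperone and unfolded protein response genes were higher for 13 of 21 and lower for 2. The increases were led by DNAJB9 (1.19 ± 0.069), HERPUD1 (1.04 ± 0.051) and the ER chaperone HSPA5 (0.98 ± 0.040), and the co-chaperone gene DNAJC3, named after its value was seen, fell (-0.17 ± 0.047). Heat shock genes went the other way, with 17 of 20 lower and 1 higher (18 lower adjusted over the list alone). HSPA8 fell from 2942 ± 44.2 to 1626 ± 51.0 CPM (-0.86 ± 0.039), and HSPH1 (-0.71 ± 0.043) and CHORDC1 (-0.63 ± 0.053) fell with it. HSPB8, named after its value was seen, was the 1 higher member (0.30 ± 0.085), and its call was lost without control replicate 1 (adjusted p = 0.055 in edgeR's quasi-likelihood test). Camera called the ATF4 list higher (adjusted p = 7.87e-13; adjusted p = 0.274 with an estimated correlation) and the ER list higher (adjusted p = 0.0151; adjusted p = 0.354 with an estimated correlation). It called the heat shock list lower (adjusted p = 6.06e-06; adjusted p = 0.274 with an estimated correlation). Counts of the ATF4 and ER lists were the same adjusted over the list alone.

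Of 23 p53 target genes, 12 were higher and 4 lower, also adjusted over the list alone, with a median of 0.19. Among members with a mean of at least 1 CPM, GDF15, the BH3-only gene BBC3 (1.73 ± 0.14) and the CDK inhibitor gene CDKN1A (0.95 ± 0.043; 302 ± 3.19 against 157 ± 2.86 CPM; SD, n = 2 libraries each) led the increases. GDF15 and BBC3 are also known targets of ATF4 or CHOP. DDB2 (-0.74 ± 0.11) and CCNG1 (-0.54 ± 0.068), named after their values were seen, were lower. Camera called the list higher (adjusted p = 0.0305; adjusted p = 0.415 with an estimated correlation), and the adjusted p was 0.0587 without APA replicate 1, 0.0721 without control replicate 1 and 0.0576 on log2(FPKM + 1) values. Among 12 pro-apoptotic BCL2 family genes, 4 were higher, with BMF (2.03 ± 0.26), BBC3 and PMAIP1 (0.61 ± 0.064) leading, and 3 lower (camera adjusted p = 0.533). Among 10 anti-apoptotic genes, 6 were higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.319), with BIRC3 higher (0.64 ± 0.048) and the mitotic survivin gene BIRC5 lower (-1.56 ± 0.054). The pro-apoptotic counts were the same adjusted over the list alone.

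NRF2 target genes, which serve the response to oxidants, were higher for 21 of 25 and lower for 0, with a median of 0.47 and the same counts adjusted over the list alone. Aldo-keto reductase AKR1C1 rose 3.92-fold (75.1 ± 1.20 against 19.1 ± 2.32 CPM; SD, n = 2 libraries each), heme oxygenase HMOX1 3.10-fold (1.63 ± 0.085) and sulfiredoxin SRXN1 2.43-fold (1.28 ± 0.046). Camera called the list higher (adjusted p = 2.47e-07; adjusted p = 0.274 with an estimated correlation). Aryl hydrocarbon receptor targets were higher for 6 of 9, led by SERPINB2 (1.34 ± 0.059) and AHRR (0.98 ± 0.19). CYP1A1, the receptor's classical target enzyme, was lower (-0.97 ± 0.24). NQO1 (0.75 ± 0.040), named after its value was seen, is also an NRF2 target. That list was called higher (camera adjusted p = 0.0255; adjusted p = 0.402 with an estimated correlation), but not without APA replicate 1 (0.0556) or without a filter on low counts (0.0527). Autophagy and lysosome genes were higher for 14 of 27, among them the autophagy receptor SQSTM1 (3291 ± 228 against 1008 ± 12.2 CPM; 1.71 ± 0.042), WIPI1 (1.27 ± 0.066) and MAP1LC3B (1.23 ± 0.045). Camera called the list higher (adjusted p = 0.0156; adjusted p = 0.415 with an estimated correlation; 0.0513 without control replicate 2), with a small median of 0.10. The 1 lower member, ATP6V1A (-0.14 ± 0.052), named after its value was seen, lost its call when APA replicate 1, control replicate 1 or control replicate 2 was left out (adjusted p 0.0932 to 0.114 in edgeR's quasi-likelihood test). Adjusted over the list alone, counts of the receptor and autophagy lists were the same.

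NF-kB inflammatory genes were higher for 21 of 26 and lower for 1, with a median of 0.66, also adjusted over the list alone. PTGS2 rose from 29.8 ± 2.38 to 190 ± 7.28 CPM (SD, n = 2 libraries each), IL1A from 1.13 ± 0.321 to 6.42 ± 1.02 CPM and CXCL2 from 1.88 ± 0.246 to 9.74 ± 0.475 CPM. NFKBIA, which encodes the NF-kB inhibitor and was named after its value was seen, was the lower member (-0.55 ± 0.061). Camera called the list higher (adjusted p = 4.79e-07; adjusted p = 0.274 with an estimated correlation). Interferon response genes were divided, with 10 of 29 higher and 6 lower (camera adjusted p = 0.497), IRF9 among the former (0.75 ± 0.091) and IFIT1 among the latter (-0.77 ± 0.096). MHC class I genes showed 5 of 13 higher, including TAP1 (0.59 ± 0.068) and HLA-B (0.27 ± 0.047), and 1 lower, TAPBP (-0.20 ± 0.044), which was named after its value was seen (camera adjusted p = 0.271). Counts of both these lists were the same adjusted over the list alone.

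Of 18 glycolysis genes, 15 were lower and 1 higher (15 and 2 adjusted over the list alone), with a median of -0.41. Lactate dehydrogenase A (LDHA) fell from 2432 ± 41.5 to 1012 ± 0.501 CPM (SD, n = 2 libraries each; -1.26 ± 0.040), and PFKL (-0.91 ± 0.053) and PGK1 (-0.78 ± 0.040) fell with it. Hexokinase HK1, named after its value was seen, rose (0.36 ± 0.041). Of 54 nuclear-encoded subunits of the respiratory chain, 28 were lower, 2 higher and 24 not called, with a median of -0.14. The decreases were led by the ATP synthase subunits ATP5MC3 (-0.52 ± 0.046), ATP5F1D (-0.46 ± 0.070) and ATP5MC1 (-0.46 ± 0.062). Cholesterol synthesis genes were higher for 18 of 25 and lower for 0 (18 and 1 adjusted over the list alone), with a median of 0.23, including MSMO1 (1.07 ± 0.044), TM7SF2 (16.6 ± 0.711 against 8.32 ± 0.259 CPM) and CYP51A1 (0.66 ± 0.043). Camera called glycolysis lower (adjusted p = 8.55e-05; adjusted p = 0.415 with an estimated correlation) and respiratory subunits lower (adjusted p = 0.00026; adjusted p = 0.304 with an estimated correlation). It called cholesterol synthesis higher (adjusted p = 0.000508; adjusted p = 0.274 with an estimated correlation). Fatty acid synthesis genes went both ways, 5 of 15 each, with SREBF1 lower (-0.85 ± 0.069) and ME1 (0.77 ± 0.054) and ACSS2 (0.67 ± 0.061) higher (camera adjusted p = 0.922). Hypoxia response genes were also divided, 9 higher and 9 lower of 23 (9 and 10 adjusted over the list alone; camera adjusted p = 0.735), LOX (1.61 ± 0.048) and SLC2A3 (1.48 ± 0.047) rising and EGLN3 (-0.94 ± 0.14) falling. Median and test of the hypoxia list pointed up and its mean down, the mean being set by the fitted value of CA9, which depends on a prior count. Counts of the respiratory and fatty acid lists were the same adjusted over the list alone.

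**Figure D3:**
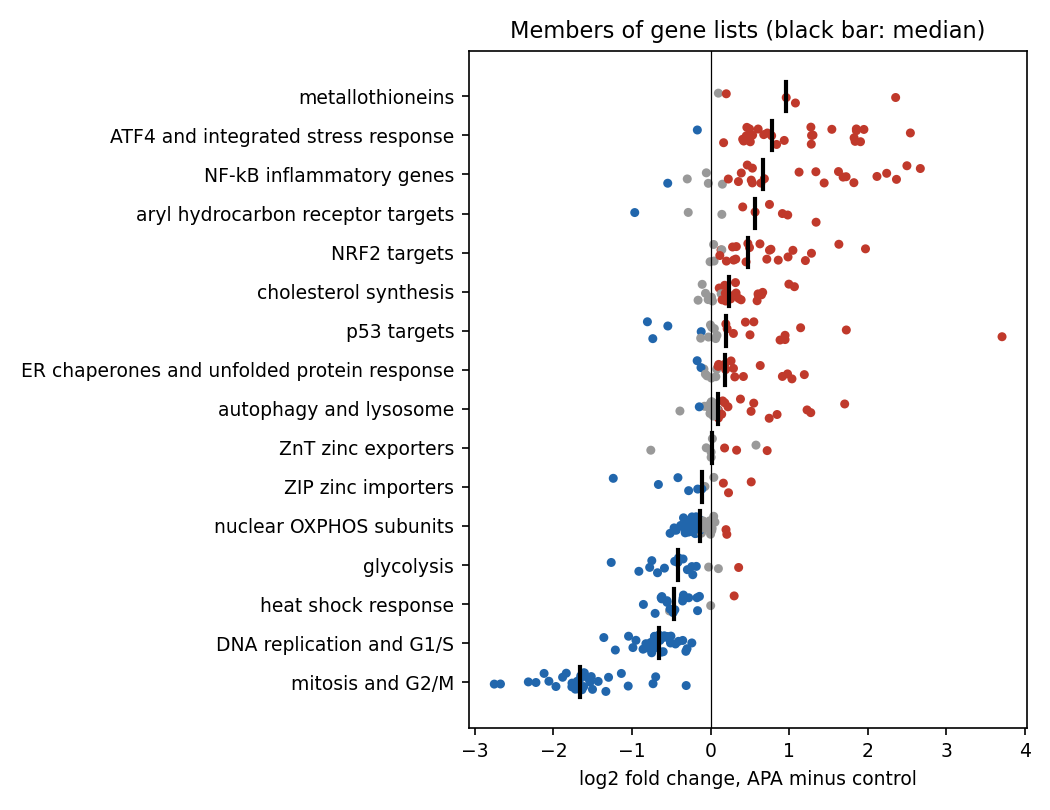
Log2 fold change (APA minus control) of each tested member of the 14 gene lists that camera called and of the ZIP and ZnT lists, with members called higher in red, called lower in blue and not called in grey, and a black bar at each list's median. Medians run from -1.66 for mitosis and -0.65 for DNA replication to 0.78 for the ATF4 list and 0.96 for metallothioneins.

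The remaining lists were not called by camera with the preset correlation. YAP and TEAD targets were higher for 11 of 20 and lower for 3 (adjusted p = 0.057), with IGFBP3 (1.77 ± 0.058), GADD45B (0.68 ± 0.071) and DLC1 (0.67 ± 0.045) leading. Outputs of the ERK pathway were higher for 13 of 23 and lower for 6 (7 lower adjusted over the list alone; camera adjusted p = 0.119), with DUSP5 (1.62 ± 0.045) and EGR1 (1.14 ± 0.064) higher and SPRY1 (-0.82 ± 0.075) lower. MYC itself was higher (0.79 ± 0.044), as was ODC1 (0.81 ± 0.041). In contrast, 18 of the 29 genes on the MYC target and ribosome biogenesis list were lower, NOP56 among them (-0.51 ± 0.045). That list includes MYC itself, and 3 members were higher, MYC and ODC1 among them (4 higher adjusted over the list alone, camera adjusted p = 0.057). Cytosolic ribosomal protein genes were higher for 34 of 74, and lower for 10 (36 and 10 adjusted over the list alone). Their increases were small, the largest being 0.41 ± 0.042 for RPS27, 0.38 ± 0.040 for RPL26 and 0.37 ± 0.043 for RPL37A. Their camera adjusted p was 0.0647, and 0.0248 without APA replicate 2.

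TGF-beta targets were divided, 6 of 17 each way (camera adjusted p = 0.891), with JUNB (1.26 ± 0.066) and SKIL (1.04 ± 0.072) higher and ID1 lower (-1.18 ± 0.067). Mesenchymal genes were higher for 5 of 19 and lower for 7 (camera adjusted p = 0.421), with SNAI2 (0.67 ± 0.066) and TNC (0.55 ± 0.043) higher and S100A4 lower (-0.81 ± 0.051). Epithelial genes were higher for 4 of 15 and lower for 5 (camera adjusted p = 0.68). The epithelial splicing regulator ESRP1 rose from 1.21 ± 0.212 to 8.78 ± 0.880 CPM (2.86 ± 0.20; SD, n = 2 libraries each), CLDN7 rose (0.76 ± 0.082) and SPINT1 fell (-0.81 ± 0.19). Medians of the TGF-beta (-0.13) and epithelial (-0.06) lists were negative, as were their tests, and their means (0.09 and 0.10) positive. Few markers of other cell types had enough counts to test. Of 5 leukocyte markers tested, CD68, also a lysosomal protein of other cells, was higher (0.74 ± 0.059; 208 ± 4.80 CPM in APA), and CSF1R (-2.41 ± 0.25) and CD14 lower (camera adjusted p = 0.69). The call of CD14 (-0.89 ± 0.34) was lost without APA replicate 1 (adjusted p = 0.147 in edgeR's quasi-likelihood test) or control replicate 1 (0.264). Of 4 fibroblast and endothelial markers, PECAM1 (-1.39 ± 0.11) and PDGFRB (-1.19 ± 0.31; adjusted p = 0.0529 in DESeq2) were lower and 0 higher (camera adjusted p = 0.224). Adjusted over the list alone, counts of the YAP, TGF-beta, mesenchymal, epithelial, leukocyte and fibroblast lists were the same.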

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

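Of the settings compared here, the correction for GC content and transcript length was chosen only after the results had been seen. The count of genes called was 7343 with RLE factors, 7255 with upper-quartile factors, 7364 without a filter on low counts, 6909 with the stricter filter, 4960 with DESeq2, 7116 with limma-voom, 5543 to 6341 on FPKM values, and 5887 to 6694 when 1 library was left out, against 7348, and each call shared with the 7348 kept its sign. Genes called past 2-fold numbered 408 with the stricter filter, 300 on log2(FPKM + 1), 424 on log2(FPKM + 0.1) and 299 on log2(FPKM + 1) without a filter, against 679 (670 to 707 with 1 library left out). Fewer genes with low counts pass the stricter filter, the pseudocounts compress their changes, and other causes were not tested. The number of lists called went from 14 to 0 with an estimated correlation (smallest unadjusted p 0.0192, adjusted 0.274) and to 28 with fry, which asks another question. The estimated correlations of heat shock (-0.0502) and NF-kB genes (0.0018) lay below the preset 0.01, so a higher correlation did not cost these lists their calls. With an estimated correlation camera tests on the 2 residual degrees of freedom, which makes small p-values hard to reach. The estimated setting also missed the list shifted in simulation (camera adjusted p = 0.185), so its lack of calls is weak evidence against a change. The camera adjusted p of metallothioneins, 0.0305, was 0.445 with an estimated correlation, 0.123 without a filter and 0.00539 to 0.0556 with 1 library left out. Fry gave adjusted p values of 0.0116 for ZIP and 0.0329 for ZnT genes, against camera's 0.368 and 0.525. Fry does not compare a list with other genes and called 28 of 36 lists, so these calls are not particular to zinc genes. Of the lists not called, YAP targets reached 0.0445 without a filter and 0.0432 on FPKM, ribosomal proteins 0.0404 and 0.0487, and MYC targets 0.0445 without a filter and 0.0498 with the GC and length correction. Of 2281 values of the 166 named genes under alternatives, 56 lost their call, 4 gained one and 0 reversed. Same-numbered libraries did not deviate together (r = -0.0171 across genes), but with 2 libraries per group and little spread this check cannot exclude pairing. The replicate number as a block gave 7120 calls, 7101 of them among the 7348. Depth limits genes such as MT1F, with under 1 CPM in control. With 2 libraries per group, the libraries left alone by a leave-out were assumed to vary like the other group's.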

Other observations

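The 16 gene families and the single genes of the first paragraphs were chosen after their values were seen, as were the tests of read sharing, heat shock, GC content and length, p53 and a single culture below. Several families defined by symbol moved together, some of which share members with the fixed lists, each with an adjusted p over the 16 families from camera. These p-values do not allow for the choice of families, or of members within them, after their values were seen. All 8 subunits of the CCT chaperonin were lower (median -0.33, adjusted p = 0.000484; adjusted p = 0.289 with an estimated correlation), with TCP1 at -0.48 ± 0.042 (SE). Of the proteasome, 27 of 37 subunits were lower and 1 higher (median -0.23, adjusted p = 0.000123; adjusted p = 0.284 with an estimated correlation), PSMD1 at -0.49 ± 0.044. Of the hnRNP genes, 19 of 21 were lower (median -0.43, adjusted p = 2.6e-07; adjusted p = 0.284 with an estimated correlation), with HNRNPA2B1 going from 1446 ± 22.0 to 897 ± 39.2 CPM (SD, n = 2 libraries each). The same held for 10 of 11 SR splicing factor genes (median -0.44, adjusted p = 0.000185; adjusted p = 0.231 with an estimated correlation), SRSF3 among them (-0.80 ± 0.12). Nucleoporin genes were lower for 20 of 21 (median -0.36, adjusted p = 7.22e-07; adjusted p = 0.231 with an estimated correlation), NUP210 at -0.59 ± 0.071. Also lower were 20 of 21 centromere protein genes (median -0.68, adjusted p = 1.03e-08; adjusted p = 0.231 with an estimated correlation) and 7 of 12 tubulin genes with 1 higher (median -0.35, adjusted p = 0.00265; adjusted p = 0.284 with an estimated correlation).

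Of 14 amino acid transporter genes, 11 were higher and 1 lower (median 0.46, camera adjusted p = 0.000134, and 0.231 with an estimated correlation). These were single symbols picked from several SLC families, so the counts do not describe all such transporters. Some of them are also on the ATF4 list. SLC1A4 rose from 15.05 ± 0.301 to 51.7 ± 3.76 CPM (SD, n = 2 libraries each). Cystathionine gamma-lyase (CTH), which makes cysteine, rose 3.92-fold (1.97 ± 0.061). Cytosolic aminoacyl-tRNA synthetase genes were higher for 12 of 20 and lower for 6 (median 0.34, adjusted p = 0.0306; adjusted p = 0.313 with an estimated correlation), while their mitochondrial counterparts were higher for 3 of 17 and lower for 6 (adjusted p = 0.383), a difference that was not itself tested. KLF transcription factor genes were higher for 11 of 15 and lower for 1 (median 0.63, adjusted p = 0.00174; adjusted p = 0.231 with an estimated correlation), with KLF4 at 1.38 ± 0.056. Numbered ZNF zinc finger genes were higher for 172 of 445 and lower for 54 (median 0.13, adjusted p = 0.00315; adjusted p = 0.284 with an estimated correlation). All 4 hair keratin genes tested were higher (median 1.12, adjusted p = 0.00283; adjusted p = 0.231 with an estimated correlation), namely KRT81 (922 ± 11.8 against 406 ± 11.8 CPM), KRT83, KRT85 and KRT86, which are close in sequence. Mitochondrial ribosomal protein genes were lower for 29 of 78 and higher for 8 (adjusted p = 0.0164; adjusted p = 0.284 with an estimated correlation), and V-ATPase subunits (11 higher, 3 lower of 20; adjusted p = 0.0653) and KDM demethylases (8 higher, 2 lower of 17; adjusted p = 0.114) were not called. The cytokine gene IL11 rose 3.78-fold (1.92 ± 0.14) and the glucocorticoid-induced gene FKBP5 fell 2.18-fold (-1.12 ± 0.044).

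P2RY11 had 196 and 182 counts in the APA libraries and 0 in both control libraries. The table also lists PPAN-P2RY11, a read-through gene that spans it, with 390 and 350 counts in APA and 461 and 486 in control, and PPAN with 1145 and 1120 against 904 and 943. Summed over the 3 genes, the log2 ratio was 0.26, so the division of reads among overlapping models leaves the value of P2RY11 uncertain. U2AF1L5, a near-identical copy of U2AF1, stood at 67.4 ± 48.4 CPM in control against 20.6 ± 6.46 in APA, with 102 and 33.1 CPM in the 2 control libraries, and it was not called (adjusted p = 0.264 from edgeR).

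Of 5 metallothionein genes tested, 4 (not MT1A) and SLC30A1, known targets of the zinc sensor MTF1, were higher, and SLC39A10, known to be repressed by zinc through MTF1, was lower. As a list, metallothioneins were called by camera (adjusted p = 0.0305; adjusted p = 0.445 with an estimated correlation), and the call was lost without a filter (0.123), without APA replicate 1 (0.0556) and without control replicate 2 (0.0513). Reads that only moved between metallothionein genes would leave their sum unchanged, but the summed metallothionein CPM rose by a log2 ratio of 0.3772, beyond the replicate SDs of 0.077 and 0.067. A proteotoxic metal stress that acts through a heat shock response still active at 24 h would raise heat shock genes, and 17 of 20 were lower and 1 higher. Their median was -0.4656, with a camera adjusted p = 6.06e-06 (adjusted p = 0.274 with an estimated correlation). Only 24 h was sampled, so an earlier response that had ended by then is not excluded. Other stress lists rose, with 21 of 25 NRF2 targets higher and 0 lower, and 28 of 29 ATF4 list genes higher and 1 lower. Metal stress without a heat shock response is therefore not excluded either. A rise of labile zinc that acts through MTF1 may account for the directions, as a hypothesis that was not tested, since zinc was not measured here. MT2A, the most abundant of the 4, rose least (0.20 ± 0.041), and the importer gene SLC39A14 rose (0.52 ± 0.043). Other causes of these changes were not tested either.

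Genes of replication and mitosis were lower together. A bias from GC content and transcript length would lower other genes of the same content and length too, but 334 genes matched to the mitosis list had a median of 0.03444 (SD 0.397), against -1.66 for that list. For replication, 331 matched genes had a median of -0.019 (SD 0.507), against -0.65, so such a bias was argued against. Activation of p53 could lower such genes, but the line is known to carry a mutant p53, and among 18 p53 targets that are not also targets of ATF4 or CHOP, 8 were higher and 4 lower, with a median of 0.073 and a camera p of 0.195, which leaves that explanation open. Slower proliferation by another route also stays open, as cell numbers and cycle phases were not measured here.

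Calls covered 53.5% of the genes tested. A single library sequenced 2 times in each group would differ by sampling noise alone, near 1, but over genes with whole counts in every library the chi-square per degree of freedom was 2.658 in APA and 1.737 in control. Replicates prepared from a single culture stay open: the coefficient of variation between them was 3.094%, and separate cultures of one line handled side by side could give a value as low. The small spread may thus be technical, and it makes small changes pass the test, as the median absolute log2 fold change of 0.36 among called genes shows. For this and the patterns above, a vehicle effect cannot be told apart from that of APA if the vehicle differed between the groups.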
